A study of Drosophila melanogaster with 66 samples.

How the data were processed

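Total RNA of imaginal discs from larvae of Drosophila melanogaster was labelled with biotin and hybridized to microarrays in a genome round (13450 features) and a focused round (1387 features, each in 4 on-array blocks). Each sample pooled at least 60 discs, with up to 100 on the genome arrays and up to 250 on the focused arrays. The labels list 66 samples: each of the 4 focused groups has 12 (3 arrays with 4 blocks), and each of the 3 genome groups has 6 (3 biological samples hybridized 2 times). The labels do not say which genome arrays share a biological sample.

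The deposited tables hold intensity on a linear scale with negative values (12.1% of the focused and 16.9% of the genome values), so a background or mismatch signal had been subtracted before the tables were deposited; the method is not stated. In the focused table the authors had scaled the arrays within each group and not between groups, since the column means differed little within groups and had a median of 282 in wing, 333 in Cbx, 184 in vg and 317 in haltere. The genome table had no scaling between arrays, with medians from 95 to 607 that followed the brightness of the scanner files (r = 0.965 on the log scale, across arrays). The scanner files give signal intensity per spot, per the file headers, for 193615 focused and 195937 genome spots, without spot names. The plan made before the data were examined was to start from the scanner files. Because no spot could be named, all tests ran on the deposited tables instead, and the scanner files served to check brightness and replicates. The groups, comparisons, gene lists, rule for named genes, threshold and most alternatives were fixed before the data were examined; the floor, and the alternatives said to be added, were not.

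The 4 block values of a focused array were averaged to 1 value, so that n counts arrays. Within each design, arrays were scaled to a common median and quantile normalized. Values under a floor were set to it, the floor being the median size of the negative values (18.7 on the focused and 58.5 on the genome arrays; 21.4% and 31.0% of values lay at or under it). Values were then taken to log2. A feature was tested if it lay above the floor on all arrays of at least 1 group, and of several probes for a gene the brightest was kept (38 genome probes were left out). Where all arrays of a group lie at the floor, a fold is given as a lower bound. Where only some arrays of a group lie at the floor, the fitted difference and its SE are given. Such a difference may be smaller than the real one and its SE too small. Gene symbols came from the annotation of the array platforms, updated through gene identifiers to the RefSeq annotation of the Release 6 plus ISO1 MT assembly; 1110 focused and 9671 genome features matched. Features named for several genes (4 and 68) or none (244 and 3303) are called by their probe number.

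Each design was fitted in limma 3.58.1 under R 4.3.3 with all groups in 1 model (lmFit, eBayes), and p-values, which are 2-sided, were adjusted over all tested features by the Benjamini-Hochberg method with a threshold of 0.05. Comparisons were haltere, Cbx and vg each minus wing, and the direct differences between them. Errors are the moderated standard errors, which rest on 1 spread per gene pooled over all groups of a design. The haltere arrays spread more than the other focused arrays. Errors and p-values of comparisons with haltere therefore tend to be too small, and those of other focused comparisons larger than their own arrays would give. A feature called in haltere minus wing and in Cbx minus wing in the same direction entered the UBX-responsive class, and it was counted as beyond vg if Cbx minus vg passed in that direction too. The name of the class states what the design seeks, since Ubx was not measured and Cbx minus vg does not remove an effect of the Cbx stock. Overlaps were set against independent lists of the same sizes, and the covariance of changes against 50 simulations of unchanged groups that share the wing arrays. Each simulated array had the spread pooled over all groups. The wing arrays spread less than this in the focused round and more in the genome round, so the simulated covariances are approximate. Relations between array rounds used Pearson and Spearman correlation across genes with 10000 permutations of genes. Scanner files were read and figures drawn with Python 3.11.15.

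The gene lists covered Hox genes and cofactors, wing pouch and blade, wing vein and intervein, wing margin and sensory organs, genes reported as UBX responsive in the haltere disc, notum and hinge, the Wnt, Dpp, Hedgehog, Notch and EGFR pathways, ecdysone response, S phase and cell cycle, cell death and JNK, heat shock, immune genes and sex markers. Markers of other cells covered adult muscle precursors, trachea, leg disc, fat body, blood cells, neurons, larval muscle and salivary gland. Several genes sit in more than 1 list, such as kn in the pouch, vein, Hedgehog and UBX-responsive lists, and many are also expressed in discs. Members were counted with p-values adjusted over all genes and adjusted over the list alone. Lists with at least 5 tested members were tested with camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. The focused array may hold genes that the study picked from an earlier round, so counts and list tests on it are not independent evidence.

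Named genes were set by rule. For each comparison with wing they are the 8 largest increases and the 8 largest decreases among called genes whose arrays do not overlap between the groups, and apart from these the 2 largest in each direction among unnamed or CG-numbered genes. They also include up to 4 members of each list with a called member, with some members that did not pass, the 4 largest in each direction in direct comparisons, and Ubx and vg throughout, with y and w as strain markers.

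The pipeline was tested on simulated data in which 200 genes were changed in arrays of unequal brightness. Each gene had 1 spread, pooled over all groups. The real groups differed in spread, the haltere arrays being widest on the focused arrays, so the shares that follow are approximate. In haltere minus wing it recovered 73.1%, 85.1% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold, with 5.56% false among the calls. In Cbx minus wing false calls were 12.3% and in vg minus wing 8.65% on the focused arrays, above the nominal share, and 4.94% and 4.52% on the genome arrays, where 44.8% and 40.3% of genes changed 1.5-fold were recovered. Alternatives covered other scalings (median, least changed genes, cyclic loess, none), fits of the 2 groups alone, stricter thresholds, eBayes with trend and robust options, a filter on dim genes, single on-array blocks, blocks as separate values, each array left out in turn, and 100 drawn pairings of the genome arrays. Added after the data were seen were a lower and a doubled floor, a generalized log, no filter on dim genes, array weights, and list tests on the genome arrays averaged in the drawn pairings.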

Results

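The study profiled RNA from imaginal discs, the larval sacs of epithelium from which the adult wing and haltere form. The haltere is the small balancing organ of the third thoracic segment of the fly. Its disc expresses the Hox protein UBX, whereas the wing disc of the yw strain serves as the reference without UBX in its wing-forming field. Cbx1 is a dominant Ubx allele that expresses UBX in the wing disc, and vg83b27 is an allele of vestigial whose wing discs lose most of the wing field. The focused round used an array of 1387 features in 4 blocks and held yw wing, yw haltere, Cbx1/MKRS wing and vg83b27 wing discs, with 3 arrays for each group. The genome round used an array of 13450 features and held yw wing, Cbx1/MKRS wing and vg83b27 wing discs, with 6 arrays for each group from 3 biological samples hybridized 2 times. The haltere was not part of the genome round. Arrays give no counts, so the number of arrays limits the precision. The median scanner signal per spot lay between 151.5 and 225.0 on the focused arrays and between 143.5 and 1060 on the genome arrays. After the floor on dim signals, 1115 focused features (899 with a gene name) and 9015 genome features (6851 with a gene name) were tested. Differences are given as log2 ± SE.

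The gene vg was measured on both array designs and comes first, because the vg83b27 stock carries a mutation in it. On the focused arrays its log2 level was 9.49 in wing, 9.30 in Cbx, 8.57 in haltere and 7.65 in vg discs, with n = 3 arrays for each. It was 3.59-fold lower in the vg mutant than in wing (-1.85 ± 0.12) and 1.90-fold lower in haltere than in wing (-0.92 ± 0.12). On the genome arrays it was 1.65-fold lower in the vg mutant (-0.73 ± 0.15, 6 arrays of 3 samples taken as independent). With the arrays averaged in pairs drawn at random, it passed in 95% of 100 drawn pairings, the true pairs being unknown. In Cbx minus wing the difference was -0.20 ± 0.12 on the focused arrays (adjusted p = 0.325) and -0.41 ± 0.15 on the genome arrays (adjusted p = 0.0944), neither past the threshold. No feature of either design was named Ubx, so Ubx is not analysed here. The strain marker w was not analysed here either. The strain marker y, named on the genome array alone, had a log2 level of 7.95 in wing, 8.96 in Cbx and 7.95 in vg discs, and its rise in Cbx was 1.02 ± 0.33 (adjusted p = 0.0499). The size rests in part on wing array 3, the only array with y at the floor: without it the rise was 0.61, still past the threshold. The call ended with 14 of the 18 arrays left out in turn, and adjusted p reached 0.444 among all alternatives, on deposited values; the cause was not tested.

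Haltere discs against wing discs ask which genes differ between the homologous organs. Cpr47Ee (CG13222), a structural protein of cuticle, was above the floor in all 3 haltere arrays and at the floor in all 3 wing arrays, at least 14.3-fold higher. The chitinase gene Cht5 rose 4.48-fold (2.16 ± 0.19) and the homeobox gene zen 3.82-fold (1.93 ± 0.28). The opposite pattern held for ana (CG8084), which codes for a secreted glycoprotein and was at least 11.9-fold lower in haltere, and for kn (CG10197), a transcription factor of the central intervein region of the wing, at least 4.87-fold lower. Cpr49Ah, another cuticle protein gene, fell by 2.78 ± 0.30 on the log2 scale, Cyp310a1 fell by 2.62 ± 0.41 and eEF1alpha2, a translation elongation factor, fell by 2.21 ± 0.13.

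Of 13 wing pouch and blade genes measured in haltere, 7 fell, 0 rose and 6 did not pass the test, and the count adjusted over the list alone was also 7. Besides kn and vg they included the homeobox gene Dll (-1.42 ± 0.12), which patterns the distal limb, and the POU-domain genes pdm2 (2-fold lower, log2 SE 0.11) and nub (-0.96 ± 0.26). The list test gave adjusted p = 0.000844, and adjusted p = 0.258 with an estimated correlation. The salm and salr genes of the same list differed by -0.04 and 0.05. Of 8 vein and intervein genes 2 fell, kn and the vein repressor net (-1.29 ± 0.26), and 4 fell adjusted over the list alone. Their list test gave adjusted p = 0.0324, and adjusted p = 0.258 with an estimated correlation, and on these focused arrays it was 0.0687 without haltere array 2, 0.0613 without haltere array 3 and 0.0675 with median scaling.

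Notch pathway genes went both ways in haltere discs on the focused arrays. Of 12 measured, 5 rose and 2 fell, with the same counts adjusted over the list alone. The genes that rose all belong to the E(spl) complex, direct targets of Notch, with E(spl)m5-HLH (1.99 ± 0.13), E(spl)m4-BFM (1.73 ± 0.14), E(spl)mdelta-HLH (1.12 ± 0.22) and E(spl)m7-HLH (0.98 ± 0.14) among them. The glycosyltransferase gene fng, which modulates Notch at the wing margin, fell (-0.81 ± 0.08). The list test gave adjusted p = 0.0296, and adjusted p = 0.258 with an estimated correlation, and it was 0.0692 without haltere array 1 and 0.0805 without haltere array 2. Of 11 notum and hinge genes 2 rose, the homeobox gene Dr (0.63 ± 0.10) and tsh (0.48 ± 0.09), and 3 adjusted over the list alone; the list's median was -0.03, its mean 0.14 and its test upward (adjusted p = 0.47). In the Hedgehog and compartment list hh (-0.65 ± 0.15) fell and ci (0.51 ± 0.11) rose, with 4 of 9 genes changed. In the Dpp list dpp (-0.53 ± 0.13) and Mad (-0.49 ± 0.12) fell among 11 genes. Antp, the 1 Hox gene tested, fell (-0.54 ± 0.13).

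Of 9 genes reported as UBX responsive in the haltere disc, 3 fell (kn, vg and dpp) and none of the 9 rose, and 1 rose adjusted over the list alone. The list's median was 0.04, its mean -0.27 and its test downward (adjusted p = 0.47). The members below the threshold included ac (0.63) and sc (0.25), proneural genes, and salm (-0.04). Among markers of other cells, leg disc genes gave 2 higher (odd, 0.57 ± 0.13, and sob, 0.53 ± 0.09) and 1 lower (dac, -0.70 ± 0.19) of 8, and zfh1, a gene of adult muscle precursors, fell to the floor. In all, 144 of 1115 genes passed, 70 higher and 74 lower, and 44 of them differed at least 2-fold. Of the 40 called genes that the naming rule gave, 28 stayed called whichever 1 array was left out, and the exceptions included nub, Antp, dpp, Mad, hh, ci, dac and odd. Array 3 of the haltere group lay far from its group-mates, and without it 234 genes passed, while 80, 95 and 93 passed without wing array 1, 2 or 3. With only haltere and wing in the fit 52 passed, 26 in each direction, all among the 144. On the values as deposited, which the authors scaled within each group, the median of all genes moved by 0.21 and 302 genes passed, 266 higher and 36 lower.

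**Figure D1:**
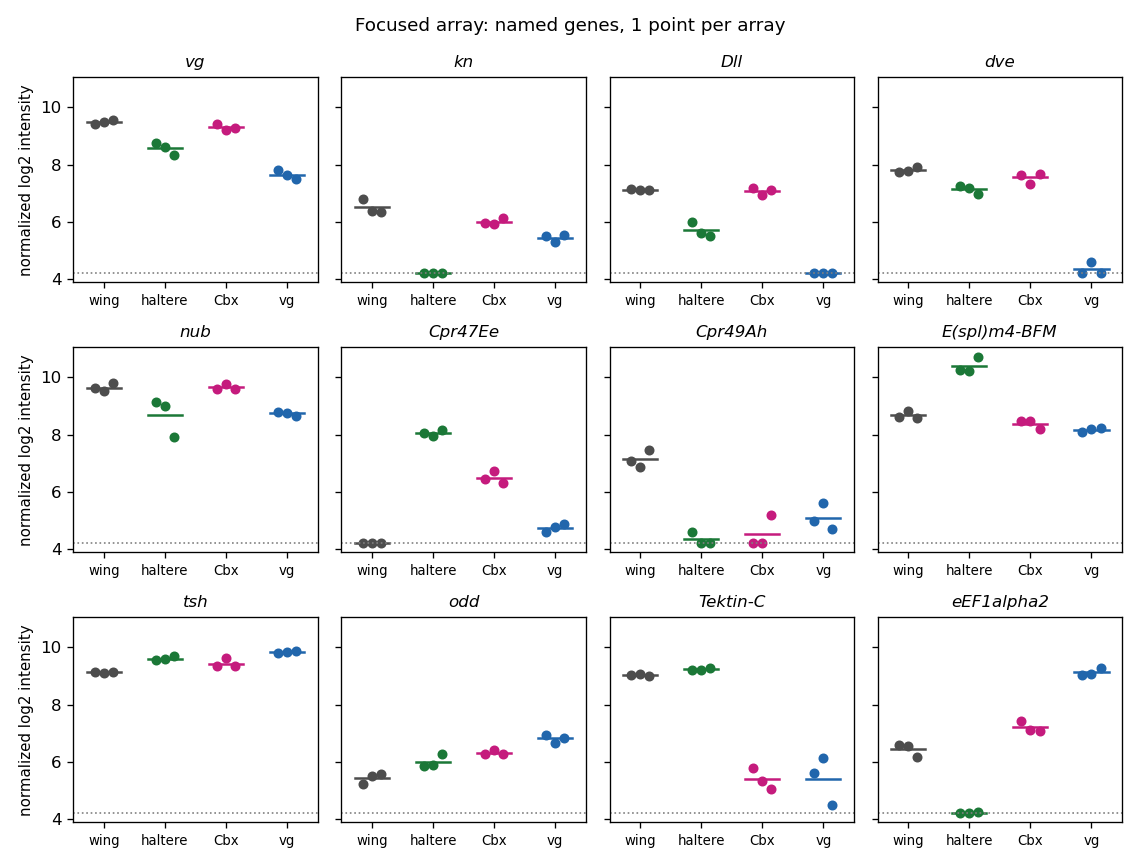
Normalized log2 intensity of 12 genes on the focused arrays, with 1 point for each of the 3 arrays per group, a bar at the group mean and a dotted line at the floor. Of the 4 groups, kn is at the floor in haltere alone and Dll in vg alone, Cpr47Ee is at the floor in wing alone, and Tektin-C lies near 9 in wing and haltere and near 5.4 in both mutants.

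Wing discs of the Cbx1 stock against yw wing discs ask which genes differ when the wing disc carries an allele that expresses UBX there. The stock also differs from yw in MKRS and in its background. These cannot be told apart from Cbx1, so a difference need not be a response to UBX. Cpr47Ee was again at the floor in wing and above it in all 3 Cbx arrays, at least 4.85-fold higher, and the transporter gene MFS14 was at least 2.58 log2 units higher. The DNA repair gene gkt rose 5.44-fold (2.44 ± 0.22), mthl8, a G protein-coupled receptor, 5.02-fold (2.33 ± 0.21), and Ski6, a subunit of the RNA exosome, 3.85-fold (1.94 ± 0.11). The axoneme gene Tektin-C (CG10541) was 12.5-fold lower (-3.64 ± 0.34), the cytochrome P450 gene Cyp4p2 fell to the floor, at least 12.2-fold lower, and Cpr49Ah fell by 2.59 ± 0.30. The transcription factor gene gem fell as well (-1.62 ± 0.12).

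Of 11 notum and hinge genes 4 rose in the Cbx discs and 0 fell, with 7 higher adjusted over the list alone. They were sr (0.75 ± 0.19), B-H1 (0.58 ± 0.08), Dr (0.33 ± 0.10) and tsh (0.30 ± 0.09). Their list test gave adjusted p = 0.00614, and adjusted p = 0.504 with an estimated correlation. Of 13 pouch and blade genes 1 fell, kn (-0.50 ± 0.12), and 12 did not pass, among them Dll (-0.06), nub (0.01) and dve (-0.25). The list test of the pouch genes gave adjusted p = 0.578. In the Hedgehog list en (-0.60 ± 0.10), inv (-0.46 ± 0.13) and kn fell, 3 of 9, and en and inv mark the posterior compartment. Of the 12 Notch genes 1 fell, kuz (-0.36 ± 0.11), and 0 adjusted over the list alone. Antp rose (0.61 ± 0.13). Of 9 genes reported as UBX responsive 1 fell, kn, and 2 adjusted over the list alone, with a median of 0.04, a mean of 0.02 and a downward test (adjusted p = 0.853). Of 8 vein genes ct (0.65 ± 0.19) and ara (0.38 ± 0.11) rose and kn fell. Leg disc markers gave 3 higher (odd, dac and sob, 0.69 to 0.88) and 1 lower (Sp1, -0.92 ± 0.24) of 8.

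On the focused arrays 200 of 1115 genes passed in Cbx minus wing, 92 higher and 108 lower, 44 of them at least 2-fold. Of 38 called genes that the naming rule gave, 24 stayed called whichever 1 array was left out, and all 4 called notum and hinge genes except B-H1 were among those that did not. Without haltere array 3, which enters through the shared estimate of spread, 362 genes passed; without wing array 1, 2 or 3 there were 109, 126 and 121, and without Cbx array 1, 2 or 3 there were 119, 126 and 114. On the values as deposited the median of all genes moved by 0.28 and 416 genes passed, 363 higher and 53 lower.

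The genome arrays extend Cbx minus wing to 9015 features. Ski6 rose 5.61-fold (2.49 ± 0.25, 6 arrays of 3 samples taken as independent), the ubiquinone synthesis gene Coq6 3.94-fold (1.98 ± 0.23) and the glycolytic gene Pglym78 3.87-fold (1.95 ± 0.23), and Cpr47Ee rose 2.62-fold (1.39 ± 0.13). Cyp4p2 was 8.84-fold lower (-3.14 ± 0.18), and the neprilysin gene Nep2 fell by 2.15 ± 0.21. The T-box gene Doc1 fell by 1.42 ± 0.14, the 1 lower gene among 12 of the pouch and blade list, whose test gave adjusted p = 0.132. Of 9 notum and hinge genes eyg (1.68 ± 0.32) rose and pnr rose from the floor, at least 1.95-fold. Of those that rose on the focused arrays, sr (-0.17), B-H1 (0.0006) and tsh were not called here, and Dr was not tested by name. Of 12 ecdysone genes 3 rose, Eip93F (0.90 ± 0.25), ftz-f1 (0.88 ± 0.22) and ImpL2 (0.76 ± 0.18), with 4 adjusted over the list alone. The muscle precursor markers zfh1 (0.73 ± 0.17) and twi (0.68 ± 0.11) rose, 2 of 4. None of the lists of at least 5 genes passed the list test here, where the lowest adjusted p was 0.132.

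In all, 1099 genome features passed in Cbx minus wing, 605 higher and 494 lower. The p-values are too small, because pairs of arrays share an RNA sample and the files do not say which. Over 100 random ways of averaging the arrays in pairs, 351 to 1272 features passed and 216 passed under all. A drawn pair may join arrays of different samples, so counts and shares over such pairings do not measure support from 3 independent samples. Ski6, Coq6, Pglym78, Cpr47Ee, Cyp4p2, Nep2, Doc1, pnr and twi were called under all 100. Averaged in pairs, eyg was called in 99% of the pairings, ftz-f1 in 85%, Eip93F in 79%, ImpL2 in 86% and zfh1 in 91%. On the values as deposited, 33 features passed, 10 higher and 23 lower, with a median shift of -0.16.

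Wing discs of the vg mutant are the comparison for loss of the wing field. On the focused arrays Map205 (CG1483), which codes for a microtubule-binding protein, fell to the floor, at least 26.2-fold lower than in wing. So did Cyp310a1, at least 14.3-fold, and the Ets transcription factor gene Ets21C, at least 10.4-fold. Tektin-C was 12.3-fold lower (-3.62 ± 0.34), as in Cbx discs, the aminopeptidase gene ApepP 11.2-fold (-3.48 ± 0.12) and the homeobox gene dve 10.9-fold (-3.45 ± 0.14). The piRNA factor krimp rose from the floor, at least 9.56-fold, eEF1alpha2 rose 6.46-fold (2.69 ± 0.13), the ecdysone-induced receptor gene Eip78C 4.43-fold (2.15 ± 0.34) and eya 3.11-fold (1.64 ± 0.17).

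Pouch and blade genes fell in the vg mutant, 7 of 13 with 0 higher, and 7 adjusted over the list alone. They included dve, Dll (at least 7.48-fold lower), vg and kn (-1.07 ± 0.12). Their list test gave adjusted p = 3.7e-05, and adjusted p = 0.11 with an estimated correlation. Notum and hinge genes rose, 8 of 11 with 0 lower, and 9 adjusted over the list alone. Examples are ush (1.56 ± 0.45), sr (1.54 ± 0.19), eyg (1.45 ± 0.35) and pnr (0.83 ± 0.16). The list test gave adjusted p = 0.00028, and adjusted p = 0.133 with an estimated correlation. Of 9 Hedgehog and compartment genes 4 fell, kn, en (-0.76 ± 0.10), inv (-0.49 ± 0.13) and dpp (-0.49 ± 0.13). That list gave adjusted p = 0.0199, and adjusted p = 0.11 with an estimated correlation. Vein genes went both ways, 4 higher and 3 lower of 8, with ara (0.78 ± 0.11) and ct (0.68 ± 0.19) up and net (-1.46 ± 0.26) down. Leg disc markers rose, 3 of 8, odd (1.37 ± 0.13), sob (1.02 ± 0.09) and mid (0.65 ± 0.15), with 4 adjusted over the list alone. On the values as deposited mid was at -0.01. Their list test gave adjusted p = 0.0315, and adjusted p = 0.486 with an estimated correlation, and on the focused arrays it was 0.102 without haltere array 3, 0.0518 without vg array 2 and 0.059 with median scaling.

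**Figure D2:**
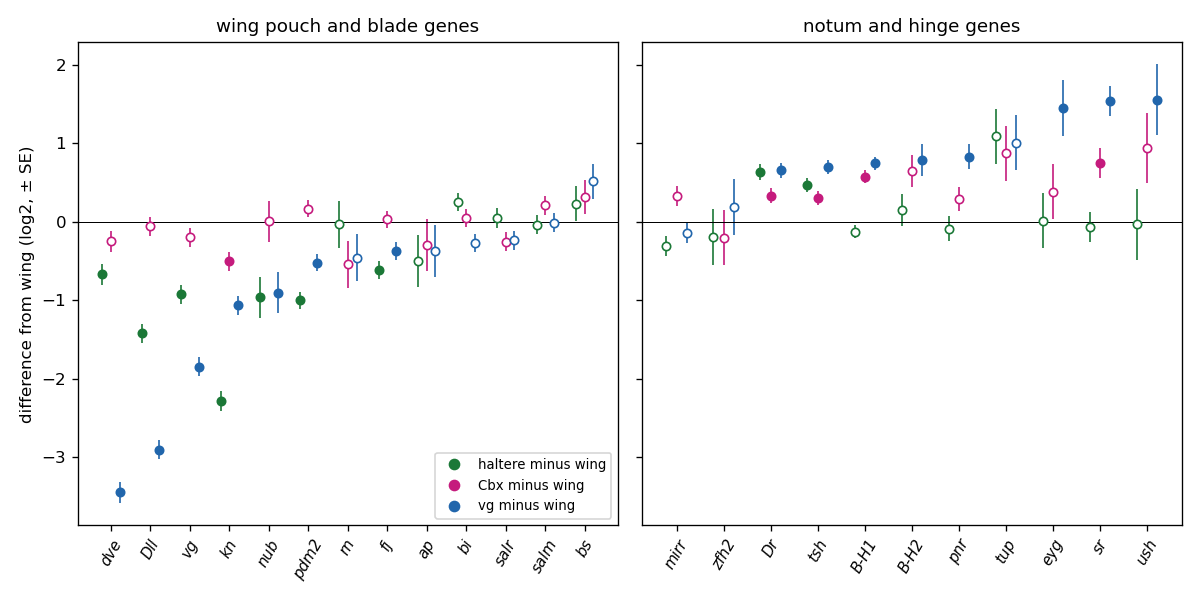
Difference from wing in log2 units, with SE as bars, for the 13 pouch and blade genes and the 11 notum and hinge genes of the focused arrays; filled points passed adjusted p under 0.05. The 7 pouch genes that passed in haltere and the 7 that passed in vg lie below 0, with dve at -3.45 in vg, while in Cbx 1 passed; the 8 notum genes that passed in vg lie above 0.

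On the focused arrays 294 of 1115 genes passed in vg minus wing, 161 higher and 133 lower, 80 at least 2-fold. Scaling on the least changed genes gave 119 higher and 153 lower, and on the values as deposited, where the median of all genes moved by -0.55, there were 24 higher and 723 lower, and the higher genes Antp, kuz, aos, Dark, bsk and mid took negative values. Of 44 called genes that the naming rule gave, 31 stayed called whichever 1 array was left out; ush, eyg, dpp, inv, ct and zfh1 were among the exceptions. Without haltere array 3, 465 genes passed, and without vg array 1, 199 did.

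On the genome arrays Cyp310a1 and Map205 fell to the floor in the vg mutant, at least 8.28-fold and 7.09-fold lower, and Dll at least 3.93-fold. The vesicular glutamate transporter gene VGlut fell by 2.55 ± 0.15, the scavenger receptor gene Sr-CII by 2.10 ± 0.21 and ApepP by 1.84 ± 0.12. The basement membrane gene SPARC rose 6.33-fold (2.66 ± 0.36), the odorant-binding protein gene Obp56a 5.64-fold (2.49 ± 0.22), and tsh rose from the floor, at least 3.57-fold. Of 12 pouch and blade genes 6 fell, Dll, Doc1 (-0.88 ± 0.14), vg and salr (-0.64 ± 0.18) among them, and 0 rose. Their list test, which takes the 6 arrays as independent, gave adjusted p = 0.000502, and adjusted p = 0.0228 with an estimated correlation. With the arrays averaged in the 100 drawn pairings it was 0.000241 to 0.00223, and 0.0615 to 0.367 with an estimated correlation, past the threshold in 0 pairings. Of 9 notum and hinge genes 2 rose, tsh and zfh2 (0.92 ± 0.16), and 2 fell, mirr (-0.53 ± 0.17) and sr (-0.41 ± 0.14), with 4 and 2 adjusted over the list alone.

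S phase genes rose in the vg mutant on the genome arrays, 4 of 13, and 4 adjusted over the list alone: Mcm5 (0.83 ± 0.17), RnrL (0.53 ± 0.16), PCNA (0.44 ± 0.11) and CycD (0.43 ± 0.13). Their list test gave adjusted p = 0.0131, and adjusted p = 0.474 with an estimated correlation. Heat shock genes rose, 3 of 5, Hsp27 (0.74 ± 0.13), Hsp26 (0.69 ± 0.16) and Hsp60A (0.68 ± 0.20), with 4 adjusted over the list alone. Their test gave adjusted p = 0.0131, and adjusted p = 0.198 with an estimated correlation. Of 9 Dpp genes 3 rose, magu (1.18 ± 0.17), sax (0.77 ± 0.19) and put (0.58 ± 0.14), at adjusted p = 0.0268, at adjusted p = 0.513 with an estimated correlation, and at 0.0682 on the genome arrays without wing array 3. The muscle precursor markers htl (0.86 ± 0.17), Him (0.86 ± 0.18) and twi (0.73 ± 0.11) rose, 3 of 4, and 3 of 9 blood cell markers rose, PPO2, eater and crq (0.51 to 0.83). Of 6 cell death and JNK genes 4 rose (Dark, egr, Dronc and bsk), and their list test gave adjusted p = 0.0908.

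In all, 1910 genome features passed in vg minus wing, 1119 higher and 791 lower, over 6 arrays that share RNA samples in pairs. Over 100 drawn pairings 395 to 2409 passed and 274 passed under all, and SPARC, Obp56a, tsh, Cyp310a1, Map205, Dll, VGlut, Sr-CII, ApepP, Doc1, magu, htl and twi were called under all 100. Median scaling gave 1391 higher and 544 lower. On the values as deposited 308 features passed, 290 higher and 18 lower, with a median shift of 0.33. Of 61 called genes that the naming rule gave, 12 lost the call when some 1 array was left out, among them RnrL, CycD, Hsp60A, Dark, bsk, crq, mirr and sr.

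Direct comparisons test the differences between these effects. In haltere minus Cbx, Tektin-C was 14.2-fold higher in haltere (3.83 ± 0.34) and Cyp4p2 was at least 13.1-fold higher, while ana was at least 12.6-fold lower and gkt 9.21-fold lower (-3.20 ± 0.22). The haltere discs had less vg than the Cbx discs (-0.73 ± 0.12), and 7 of 13 pouch genes and 6 of 8 vein genes were lower in haltere, with 7 and 6 adjusted over the list alone. Those list tests gave adjusted p = 0.0231 and 0.00897, and adjusted p = 0.396 and 0.311 with an estimated correlation. Notch genes gave 6 higher and 2 lower of 12, with 8 and 2 adjusted over the list alone, at adjusted p = 0.0247, and at adjusted p = 0.373 with an estimated correlation. In all 322 genes passed, 154 higher and 168 lower, and 165 with only the 2 groups in the fit.

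In Cbx minus vg on the focused arrays, Map205 was at least 51.4-fold higher in Cbx, ApepP 11.1-fold (3.47 ± 0.12) and dve 9.18-fold (3.20 ± 0.14), whereas Cyp4p2 was at least 54.1-fold lower and Edem1, a factor of protein quality control, 8.65-fold lower (-3.11 ± 0.29). Pouch genes were higher in Cbx, 7 of 13, with 8 adjusted over the list alone, at adjusted p = 5.74e-05, and at adjusted p = 0.223 with an estimated correlation; the genome arrays gave 6 higher and 1 lower of 12 (adjusted p = 0.245). In all 214 genes passed, 108 higher and 106 lower; without haltere array 3, 341 passed. The values as deposited gave 888 higher and 19 lower, with a median shift of 0.83. On the genome arrays Map205 was at least 13.4-fold higher, Sr-CII 7.25-fold (2.86 ± 0.21) and VGlut 6.99-fold (2.81 ± 0.15), and Cyp4p2 was 24.1-fold lower (-4.59 ± 0.18). S phase genes were lower in Cbx, 7 of 13, and 7 adjusted over the list alone, at adjusted p = 0.0138, and at adjusted p = 0.368 with an estimated correlation. In all 3780 genome features passed, 1817 higher and 1963 lower, and 2427 to 4037 over the 100 pairings; the values as deposited gave 43 higher and 1560 lower, with a median shift of -0.49.

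In haltere minus vg, Map205 was at least 19.3-fold higher in haltere, Cpr47Ee 9.88-fold (3.30 ± 0.12) and ApepP was higher by 3.25 ± 0.12, and eEF1alpha2 was 29.8-fold lower (-4.90 ± 0.13). Notum and hinge genes were lower in haltere, 6 of 11, with 6 adjusted over the list alone, at adjusted p = 0.0347, and at adjusted p = 0.385 with an estimated correlation. In all 349 genes passed, 153 higher and 196 lower, and 184 with only the 2 groups in the fit. Scaling on the least changed genes gave 200 higher and 149 lower, and the values as deposited gave 867 higher and 22 lower, with a median shift of 0.77.

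Genes that changed in the same direction in haltere and in Cbx discs form the class that the design sets out to find. It held 35 genes, 16 higher and 19 lower, of which 31 have a name. The largest changes upward were Cpr47Ee (at least 3.84 in haltere and 2.28 in Cbx) and the feature probe402 (at least 3.18 and 1.35), both at the floor in wing, and CG31365 (1.76 and 1.89). Downward they were Cpr49Ah (-2.78 and -2.59), kn, which fell to the floor in haltere (by at least 2.28, and -0.50 in Cbx), CG42268 (-2.28 and -0.82) and CG11360 (-1.54 and -1.64). Where genes lie at the floor the order by size is not exact. Members outside the rule for named genes are given because they belong to the class, and so were chosen after their values were seen. Of the 35 genes, 19 also passed in vg minus wing in the same direction. Genes of the fixed lists in the class were Dr, tsh, odd and sob (higher) and kn and Hsp60A (lower). All of these except Hsp60A changed further in vg minus wing: Dr 0.65, tsh 0.70, odd 1.37, sob 1.02 and kn -1.07. For those genes Cbx minus vg passed in the direction opposite to the class, so they are not set apart from loss of the wing field. In Cbx minus wing the calls of Dr and tsh each ended with 10 of the 12 arrays left out in turn and that of kn with 3. On the genome arrays kn was called neither in Cbx (-0.16) nor in vg (-0.20). There sob (0.17) and tsh were not called in Cbx either, while odd was (0.45). Of the 35 genes, only Cpr47Ee, Cpr49Ah and probe1230 stayed in the class under every alternative. Among these only Cpr47Ee lay beyond vg, because Cpr49Ah and probe1230 fell in vg minus wing too (-2.04 and -1.06). In 14 of the 35 the Cbx discs also lay beyond the vg discs in the same direction, 6 higher (Cpr47Ee, probe402, CG31365, Dtg, cnc and aru) and 8 lower (CG11360, CG11550, Nf-YA, CG3777, Hsp60A, DhpD, CG10341 and probe1226). Lists of these sizes drawn independently would share 12.9 genes in the same direction. The covariance of the log2 changes across genes was 0.0542, against 0.0256 simulated from the shared wing arrays alone. The simulation used the pooled spread, which the haltere arrays raise, so 0.0256 is not an exact measure of what the shared arrays give. With 3 wing arrays no split leaves 2 in each part, so part of the overlap may come from the shared arrays. A further 10 genes passed in both with opposite directions. The class held 77 genes without haltere array 3, 9, 20 and 21 without wing array 1, 2 or 3, 20 and 21 without Cbx array 1 or 3, and 23 without vg array 1. With only the 2 groups compared in each fit it held 16, 5 higher and 11 lower, and on deposited values 148, 143 higher and 5 lower, of which 20 are among the 35.

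**Figure D3:**
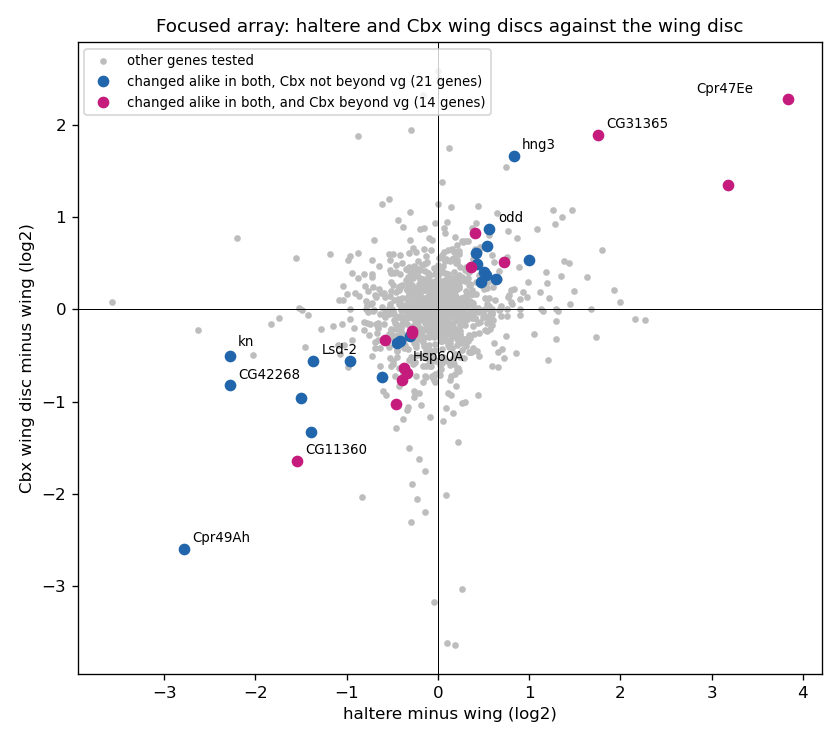
Log2 difference from wing in haltere discs (horizontal) and in Cbx wing discs (vertical) for each of the 1115 genes tested on the focused arrays. Coloured points are the 35 genes that passed in both in the same direction, with 14 that also passed in Cbx minus vg in another colour; Cpr47Ee, at the floor in wing, lies at 3.84 and 2.28 and Cpr49Ah at -2.78 and -2.59.

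The vg mutant shared more genes with each of the other groups. Haltere and vg discs had 54 genes changed in the same direction, 21 higher and 33 lower, against 18.9 for independent lists, with 19 opposite. Cbx and vg discs had 98, 52 higher and 46 lower, against 26.2 for independent lists, with 19 opposite. Tektin-C (-3.64 and -3.62), probe69 (2.50 and 2.43) and hng3 (1.67 and 2.01) had nearly the same change in both mutants on the focused arrays. The genome arrays gave smaller and less equal changes in Cbx and vg for Tektin-C (-0.77 and -1.56) and hng3 (0.87 and 1.44). On the focused arrays the covariance of Cbx and vg changes was 0.145, against 0.0254 simulated from the shared wing arrays alone. The same limit of 3 shared wing arrays applies. The genome arrays gave 190 features in the same direction in both mutants (118 for independent lists) and 76 opposite (114 for independent lists). Across all features there r was 0.068 (Spearman 0.008), and the covariance, 0.0109, was below the 0.0177 simulated from the shared wing arrays alone.

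The rounds used different arrays and samples, and 692 named genes were tested in both. Across these genes the log2 changes of Cbx minus wing had Pearson r = 0.406 (Spearman 0.318) and those of vg minus wing r = 0.505 (Spearman 0.387). Genes are not independent replicates, so these values describe the arrays. The permutation p over 10000 shuffles of genes was 1e-04 for each, the smallest they can give, and 0.000167 after adjustment over 5 such relations. Of genes called in both rounds, 64 of 71 had the same direction in Cbx minus wing (22.1 for independent lists), among them Ski6, Cpr47Ee, Cpr49Ah, Cyp4p2, Tektin-C, gkt and hng3. In vg minus wing it was 82 of 90 (33.9 for independent lists), among them Map205, Cyp310a1, Dll, ApepP, vg and Vajk2. On deposited values, which keep the shifts between groups, it was 8 of 10 in Cbx minus wing, 12 of 25 in vg minus wing, and 22 of 194 in Cbx minus vg (85 of 93 after scaling). In Cbx minus wing it was 44 of 47 without focused wing array 1 and 77 of 99 without haltere array 3. Without haltere array 3 it was 103 of 121 in vg minus wing and 120 of 142 in Cbx minus vg. The cause was not tested. Among the largest changes of the focused arrays, those of Eip78C and Ect3 in Cbx (0.13 and 0.03 on the genome arrays) and of eEF1alpha2, Eip78C and Edem1 in vg (0.40, -0.76 and 0.30) were not called on the genome arrays. The 7 opposite in Cbx included eEF1alpha2, chosen after its values were seen, which rose on the focused arrays (0.77 ± 0.13) and fell on the genome arrays (-2.95 ± 0.37), and the 8 opposite in vg included sr, which rose on the focused arrays and fell on the genome arrays. Haltere minus wing on the focused arrays and Cbx minus wing on the genome arrays share no arrays, and they had r = 0.144 (Spearman 0.078, permutation p = 4e-04, adjusted 5e-04). Of 91 haltere calls and 232 Cbx calls among the 692 genes, 29 were shared, no more than independent lists of these sizes would share in all. Of the 29 genes called in both, 20 had the same direction (15.02 for independent lists) and 9 the opposite. Cpr47Ee, Cpr49Ah, Dtg, CG11360 and CG11550 were among the 20. That count was 8 of 13 without focused wing array 1, 10 of 14 without wing array 2, 14 of 18 without wing array 3, 27 of 43 without haltere array 3 and 2 of 5 on deposited values, and the cause was not tested. With vg minus wing on the genome arrays haltere minus wing had r = 0.036 (permutation p = 0.345).

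**Figure D4:**
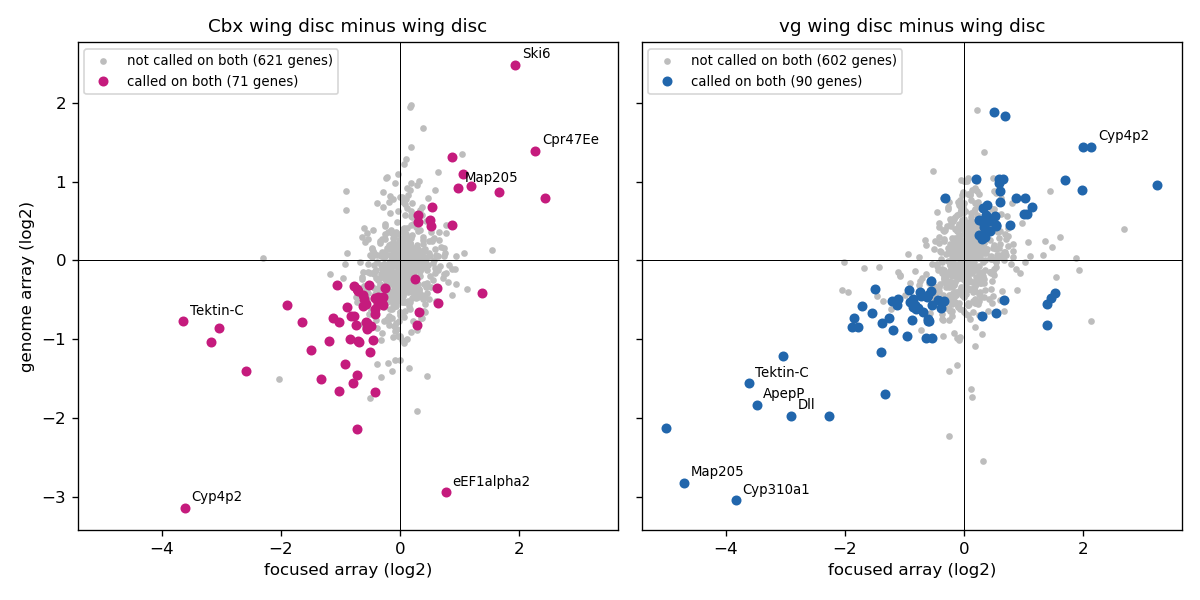
Log2 difference from wing on the focused arrays (horizontal) and on the genome arrays (vertical) for the 692 genes tested in both, in Cbx wing discs (left) and vg wing discs (right). Coloured points passed on both arrays, 71 in Cbx and 90 in vg, and most lie in the quadrants of equal sign; eEF1alpha2 in Cbx is an exception.

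Some groups fixed in advance moved little or had few members. On the focused arrays 6 EGFR genes and 6 ecdysone genes were tested; in haltere none passed, in Cbx the ecdysone list had 1 higher (Eip78C) and 1 lower (EcR), and in vg 1 of each list rose (aos and Eip78C). The Wnt list had 2 genes on the focused arrays, with 0 past the threshold in the 3 comparisons with wing, and 3 on the genome arrays, where Wnt6 rose in Cbx (0.41 ± 0.11). The immune gene Rel rose in haltere (0.51 ± 0.13), and 0 of 4 immune genes passed on the genome arrays. Trachea markers gave 0 of 1 on the focused arrays and 1 lower of 3 in genome Cbx, Gasp (-0.85 ± 0.16). Fat body gave 1 higher of 2 in genome Cbx (Fbp1, 0.57 ± 0.16), salivary gland 1 higher of 2 (Sgs4, 0.80 ± 0.20), larval muscle 1 higher of 5 (Tm2, 0.87 ± 0.20), and neurons 0 of 2. In genome vg, larval muscle gave 1 lower (Mlp60A, -0.69 ± 0.23), and fat body, salivary gland and neurons gave 0. The focused arrays tested no gene of those 4 lists. Sex markers gave 0 of 1 on the focused arrays and 0 of 3 in genome Cbx, with 1 lower in genome vg, Yp3 (-0.43 ± 0.12). Margin and sensory organ genes gave fng lower in haltere and ct higher in both mutants on the focused arrays, each 1 of 5, and on the genome arrays sc higher in Cbx (0.67 ± 0.13) and neur lower in vg (-0.44 ± 0.15), each 1 of 6.

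The remaining genome lists had few members past the threshold. In Cbx discs the UBX-responsive list gave 1 higher (sc) and 1 lower (dpp, -0.42 ± 0.14) of 8, the same dpp call was the 1 of 9 Dpp genes and 1 of 10 Hedgehog genes that fell, and Brd (-0.71 ± 0.22) was the 1 lower of 11 Notch genes. Heat shock genes gave Hsp26 higher (0.86 ± 0.16) and Hsc70-4 lower (-0.41 ± 0.11) of 5, and leg disc markers odd higher (0.45 ± 0.14) and Lim1 lower (-0.48 ± 0.14) of 10. The vein (6), EGFR (7), S phase (13), cell death (6) and blood cell (9) lists had 0 past the threshold in Cbx. In vg discs vein genes gave caup (0.89 ± 0.18) and ara (0.45 ± 0.11) higher of 6, Hedgehog genes smo and ci higher of 10, EGFR genes drk and spi higher of 7, and ImpL2 (1.53 ± 0.18) was the 1 higher of 12 ecdysone genes. Notch genes gave Brd (0.80 ± 0.22) and E(spl)m6-BFM (0.66 ± 0.19) higher and E(spl)mbeta-HLH and neur lower of 11, with a median of -0.07, a mean of 0.10 and a downward test (adjusted p = 0.749). E(spl)mbeta-HLH was at 0.03 on the values as deposited. Leg disc markers gave sob higher (0.60 ± 0.13) and al lower (-0.67 ± 0.17) of 10, the UBX-responsive list gave vg lower of 8, and the immune, Wnt and trachea lists had 0 past the threshold. In the pairings of the genome arrays dpp was called in 15% in Cbx, odd in 25%, Lim1 in 27%, Wnt6 in 37%, Brd in 40%, Hsc70-4 in 43%, Fbp1 in 46% and y in 24%, and in vg bsk was called in 13%, Dronc and sr in 34%, neur in 36%, drk in 39%, Mlp60A in 44%, mirr in 45%, smo in 46%, CycD and crq in 54%, RnrL and Yp3 in 63% and Dark in 65%.

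On the focused arrays the short lists gave Hsp60A lower in haltere (-0.37 ± 0.08) and in Cbx (-0.64 ± 0.08), and bsk higher in Cbx (0.40 ± 0.08). In vg discs Ets21C fell and Dark (0.38 ± 0.12) and bsk (0.26 ± 0.08) rose among 4 cell death genes, and zfh1 (0.69 ± 0.20) rose among 2 muscle precursor genes. The blood cell gene lz rose from the floor in vg discs, at least 1.43-fold. Notch genes in vg discs gave kuz higher and E(spl)m4-BFM (-0.49 ± 0.14) and E(spl)malpha-BFM (-0.37 ± 0.11) lower of 12, the UBX-responsive list gave vg, kn and dpp lower of 9, and dpp was the 1 lower of 11 Dpp genes. The 1 S phase gene did not pass in any comparison with wing. A list's median, mean and test differed in sign in 16 cases, among them ecdysone genes in haltere (median -0.11, mean 0.11), EGFR genes in haltere (0.03 and -0.05), Dpp genes in Cbx on the genome arrays (0.03 and -0.03), margin genes in vg (-0.04 and 0.07), Dpp genes in vg (0.10 and 0.08 with a downward test) and pouch genes in haltere minus vg (-0.03 and 0.31). None of the 16 tests passed.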

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

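No test of gaps was chosen after the result was seen. In each group of 6 genome arrays the gap between the highest or lowest array and its nearest neighbour was divided by the whole range, for each named gene and each quality measure. Chance passes the critical value for 6 arrays in about 5% of groups; here 25 of 262 groups did (9.54%). Groups of 3 focused arrays are too small for this test.

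Genome wing array 3 held the lowest value of its group, with a gap past the critical value, for Cyp4p2 (0.745), y (0.71), Dll (0.659), CycD (0.658), Dronc (0.691), sob (0.756), crq (0.696) and eEF1alpha2 (0.673). The same array had the highest scanner median (0.879) and the lowest correlation with its group-mates (0.648). In another wing array, array 4, probe1224 was highest (0.71).

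Among the genome Cbx arrays, Brd was highest in array 1 (0.669), ImpL2 lowest in array 2 (0.702), Rbm13 highest in array 3 (0.628), abs lowest in array 5 (0.662) and Lim1 highest in array 6 (0.669). In Cbx array 4 zfh1 (0.717) and E(spl)mbeta-HLH (0.72) were lowest, and the scanner median was highest (0.65). Among the genome vg arrays, magu was highest in array 1 (0.693), eater highest in array 2 (0.822) and ApepP highest in array 6 (0.641). In vg array 5 Cyp4p2 (0.717) and eEF1alpha2 (0.68) were lowest, and vg array 1 had the lowest correlation with its group-mates (0.681).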

How the results depend on the processing

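A lower and a doubled floor, the generalized log, the fit with no filter on dim genes, the array weights and the list tests on averaged pairs were chosen after seeing the data; the others had been fixed earlier. Fits without background correction, with normexp, with mismatch subtraction and with other probe summaries were not run, because spots carry no names. For the same reason the dim filter used the 20th percentile of mean values in place of control spots. Fits with scan date or slide as a block, which need no spot names, were not run either. Signal over background limits the rest: 21.4% of focused values, and a larger share of genome values, lie at or under the floor. No paired analysis was possible because discs were pooled for each array and the replicate numbers tie no array of a group to an array of another. Of the results on named genes and lists, 259 kept direction and call with median scaling and 17 lost the call; for named genes alone with cyclic loess it was 251 and 12, with scaling on the least changed genes 247 and 15, and on deposited values without scaling 173 and 79. The counts of both rounds stayed within 1.5 times under median, least changed and cyclic loess scaling, the trend and robust options, the dim filter, no filter, both floors, the generalized log and blocks as separate values. For Cbx minus wing the correlation of the array rounds across genes lay between 0.392 and 0.411, and for vg minus wing between 0.478 and 0.515; a shift of all genes cannot move it, and the shared calls did move. Except where stated, the cause was not tested.

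Without scaling between groups, on values as deposited, the calls were 302 in haltere minus wing, 416 in Cbx minus wing, 747 in vg minus wing, 907 in Cbx minus vg and 889 in haltere minus vg on the focused arrays. On the genome arrays they were 33 in Cbx minus wing, 308 in vg minus wing and 1603 in Cbx minus vg. The UBX-responsive class held 148 genes, with 137 beyond vg. With only the 2 groups compared in the fit, 52 passed in haltere minus wing, 357 in Cbx minus wing, 165 in haltere minus Cbx, 184 in haltere minus vg and 648 in genome Cbx minus wing, and the class held 16, with 8 beyond vg. At adjusted p under 0.01, a stricter threshold by construction, the focused counts were 68, 84 and 162 for haltere, Cbx and vg minus wing, 180 for haltere minus Cbx, 128 for Cbx minus vg and 207 for haltere minus vg. The genome counts were 404, 713 and 2171 for Cbx minus wing, vg minus wing and Cbx minus vg, and the class held 9, with 3 beyond vg. With at least 1.5-fold they were 90, 112, 168, 206, 130 and 218 in the same order of focused comparisons, 625, 932 and 2126 on the genome arrays, and 10 in the class, with 4 beyond vg. On-array block 1 alone gave 184 in vg minus wing, 21 in the class and 5 beyond vg. With array weights, which count arrays of larger spread less, 320, 412 and 520 passed in haltere, Cbx and vg minus wing, 497 in haltere minus Cbx and 372 in Cbx minus vg, with 101 in the class and 30 beyond vg. With the genome arrays averaged in the randomly drawn pairs, the lowest counts were 351 for Cbx minus wing, 395 for vg minus wing and 2427 for Cbx minus vg, and 216, 274 and 1921 features passed under all pairings.

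With each array left out, haltere minus wing ranged from 80 (without wing array 1) to 234 (without haltere array 3), Cbx minus wing from 109 (wing array 1) to 362 (haltere array 3), vg minus wing from 199 (vg array 1) to 465 (haltere array 3) and Cbx minus vg from 148 (vg array 1) to 341 (haltere array 3). The class ranged from 9 (wing array 1) to 77 (haltere array 3), and its part beyond vg from 4 to 24 for the same arrays. The number of lists that passed ranged from 1 (without haltere array 2) to 3 in haltere minus wing, and from 0 to 2 (without Cbx array 5) in genome Cbx minus wing. With an estimated correlation 0 lists passed in haltere, Cbx and vg minus wing on the focused arrays and 1 in vg minus wing on the genome arrays, where 0 passed with pairs averaged as well.

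Signs turned for a few named genes. In haltere minus wing odd was at -0.53 in block 2 alone. In vg minus wing CG3706 was at -0.90 in block 4 alone, bsk at -0.0368 in block 2 alone and zfh1 at -0.12 in block 3 alone. With values as deposited, Antp was at -0.0133, kuz at -0.26, aos at -0.26, Dark at -0.26, bsk at -0.35 and mid at -0.00882 in vg minus wing, vg at 0.0883 in Cbx minus wing, E(spl)mbeta-HLH at 0.03 in genome vg minus wing and vg at -0.17 in genome Cbx minus vg. The marker y, near 0 in genome vg minus wing, was at -0.0347 with scaling on the least changed genes, at -0.0269 with cyclic loess, at -0.16 with the floor at double, at -0.0280 with the generalized log and at -0.34 with array weights, and it ranged from -0.42 (without wing array 3) to 0.16 (without wing array 6).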

Other observations

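Of the tests reported here, those of a local defect, of the shared wing arrays, of the loss of the wing pouch in both mutants and of unequal brightness were chosen after the result was seen. Several strong changes lie outside the gene lists, and the genes given for them were chosen after the values were seen. On the genome arrays CG15654 was at the floor in the wing arrays and was at least 12.6-fold higher in Cbx and 11.5-fold higher in vg discs, against the same 6 wing arrays. Coq6 (1.98 ± 0.23 and 1.91 ± 0.23) and Pglym78 (1.95 ± 0.23 and 1.89 ± 0.23) rose in both mutants, and blanks, an RNA-binding factor of the testis, fell in both (-1.47 ± 0.34 and -1.74 ± 0.34). The focused arrays gave no call for Coq6 (0.20 ± 0.17 and 0.22 ± 0.17) or blanks (0.46 ± 0.48 and 0.14 ± 0.48), and for Pglym78 a call in vg (0.50 ± 0.09) and haltere discs (0.36 ± 0.09) but not in Cbx (0.17 ± 0.09). CG9021 was at least 7.97-fold higher in vg discs, and SCCRO (2.39 ± 0.32) and the transmembrane receptor gene dnt (at least 3.96-fold) rose there too. The proteolytic enzyme gene Jon99Cii (1.54 ± 0.31) and the odorant-binding protein gene Obp56d (1.35 ± 0.16) rose in Cbx discs, and Obp56d also in vg discs (1.14 ± 0.16).

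In the focused round CG18343 fell by 3.17 ± 0.22 in Cbx and 32.0-fold in vg discs, and CG11594 fell to the floor in both, at least 8.20-fold lower. Both genes fell on the genome arrays too, CG18343 at -1.03 ± 0.14 and -2.13 ± 0.14 and CG11594 at -0.86 ± 0.14 and -1.21 ± 0.14. Cyp4p2 went opposite ways in the mutants, at least 12.2-fold lower in Cbx and 4.42-fold higher in vg, and the direct difference was at least 54.1-fold. Edem1 also went opposite ways, -1.50 ± 0.29 in Cbx and 1.62 ± 0.29 in vg, with -3.11 ± 0.29 between them; on the genome arrays it fell in Cbx (-1.14 ± 0.20) and was not called in vg (0.30 ± 0.20). Genes of the focused array were called more often than others on the genome arrays, 33.3% against 10.1% in Cbx minus wing, with a median change of -0.13 against 0.00. The shares were 37.7% against 19.5% in vg minus wing and 57.2% against 40.4% in Cbx minus vg. If genes of the focused array were picked from an earlier round, such an excess follows from the choice, which could not be checked. Scaling held the median of Cbx minus wing near 0 on the focused arrays (0.02), so a shift like the -0.13 would not show there. Small rises in Cbx on the focused arrays may therefore be too large and small falls too small, which was not tested.

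Haltere array 3 of the focused round stood apart: its deviations from the mean of its group-mates had an SD of 0.819 log2 units, against 0.457 and 0.426 for the other haltere arrays and 0.209 to 0.334 for the remaining groups, with gbb (-3.11) and mey (-3.10) farthest off and a median of 0.55 over 8 leg disc markers. A local defect on the array would differ between its blocks, but the deviations had a median correlation of 0.653 across genes between the 4 blocks, higher than on any other focused array (0.545), which argues against it. A weaker signal over background would spare bright genes, but in the brightest genes the SD was 0.470, 2.71 times the highest among wing, Cbx and vg arrays (0.173). RNA of another group mixed in would turn the deviations toward that group, but the highest correlation was 0.107, with wing (0.0278 with Cbx and 0.0567 with vg). A difference between the pooled haltere samples themselves stays open and could not be tested. The number of this array also lies far from those of its group-mates, and the labels do not say what the numbers stand for.

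Cbx and vg discs shared 98 genes that changed in the same direction. The shared wing arrays as the whole cause would move these genes alike in haltere minus wing, but their median change there in the mutants' direction was 0.11 (quartiles -0.04 to 0.39) against a median size of 0.61 in Cbx and 0.68 in vg; for 19 of the 98 that passed in haltere minus wing in the same direction this stays open, and 5 passed in the opposite direction. In the pouch list 1 of the 7 genes lower in vg was lower in Cbx, which argues against a loss of the wing pouch in Cbx as large as in vg. A smaller loss in Cbx stays open, because the 4 notum and hinge genes higher in Cbx (sr, B-H1, Dr and tsh) were also higher in vg on these arrays. On the genome arrays sr (-0.17), B-H1 (0.0006) and tsh were not called in Cbx, and Dr was not tested by name. The rise of these 4 genes in Cbx thus rests on the focused arrays alone, while eyg and pnr of the same list rose on the genome arrays. The genetic background of the mutant stocks cannot be told apart from the mutations, because each stock is 1 group; on the genome arrays 58.1% of 62 of these genes had the same direction in both mutants (24 of 28 lower and 12 of 34 higher genes), against 29.5% of the other shared genes. A response common to both mutations also stays open, as untested: across all genome features the covariance of the mutants was 0.0109, below the 0.0177 simulated from shared wing arrays alone, whereas 190 called features had the same direction (118 for independent lists) and 76 the opposite (114).

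On the focused arrays each group holds its own stretch of array numbers, so an effect of array order cannot be told apart from the group there. The genome Cbx arrays carry array numbers of another series than the genome wing and vg arrays. A shift between the series of arrays cannot be told apart from the genotype on the genome arrays, because all Cbx arrays are in 1 series. Of 232 genome Cbx minus wing calls measured on the focused arrays 67.2% had the same direction, against 71.4% of 255 in vg minus wing. Unusual brightness of the Cbx arrays is argued against, since 6 of 6 had scanner medians within the range of the wing and vg arrays. This cannot exclude an effect of brightness in Cbx minus wing, because wing array 3 had a median of 1060 and its group-mates 143.5 to 254.5. The difference in genotype is the biological explanation that stays open.

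Other splits of the arrays were counted for each comparison. For the focused comparisons 3 arrays against 3 give 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave as many calls: 144 in haltere minus wing (highest other 1), 200 in Cbx minus wing (0), 294 in vg minus wing (0), 322 in haltere minus Cbx (1), 214 in Cbx minus vg (0) and 349 in haltere minus vg (1). For the genome comparisons 1 of 100 drawn splits of 12 arrays, the real one, gave as many: 1099 in Cbx minus wing (highest other 323), 1910 in vg minus wing (622) and 3780 in Cbx minus vg (103). The bound set for these splits took arrays as units, but each group has 3 samples hybridized 2 times, which allow 10 splits, so chance is not excluded there either. For the UBX-responsive class 3 of 100 splits of the 9 arrays gave 35 genes or more, with 88 and 65 in the others, whose reference is wholly another group. Of the 99 other splits 93 gave 0 genes, because mixed groups yield few calls, so this shows that the groups differ and decides nothing about changes shared by haltere and Cbx.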
